A study of Ovis aries with 3 samples.

How the data were processed

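The deposited files hold raw counts, whole numbers of UMIs per gene and barcode, 1 matrix for each of 3 libraries. Nuclei had been isolated from frozen placenta on an iodixanol gradient and sequenced as 3' droplet libraries, per the labels' protocols. The authors had run Cell Ranger, version 6.1.0 per the file headers and version 2.1.1 per the submitters' processing notes, and the conflict could not be resolved. The genome build and annotation are not given in the sources used here, so no coordinates are given. Dense tables deposited beside the matrices matched them in every value of all 22779 gene rows in each library, and were not used further. A symbol was taken only where the files pair one with an identifier. CYP19A1 and GH1 of the fixed lists were matched to CYP19 and GH through synonyms in a RefSeq table of assembly ARS-UI_Ramb_v3.0.

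Barcodes with fewer than 300 genes (none) or over 5% mitochondrial UMIs (148, 48 and 19) were removed. Doublets were scored against simulated doublets within each library, and the highest-scoring 6.78%, 8.60% and 6.31% were removed, a fixed rate of 0.8% per 1000 nuclei. Counts were scaled to 10000 per nucleus and log-transformed. Then 2000 variable genes, 30 principal components, an exact 15-nearest-neighbour graph and Leiden clustering at resolution 1 were used, with no batch correction. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

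Markers, gene lists, comparisons and the rule for named genes were fixed before the data were examined. The scoring of clusters was not. A marker supported a cluster when its CPM reached 1/3 of the highest CPM among clusters of at least 50 nuclei, with at least 20 UMIs, and 3 markers were needed. That fraction was chosen after cluster values had been seen, because 1/4 would have called the KDR-marked cluster 8 trophoblast. The need for PAG4, PAG6 and PAG9 together was also set then, as were the sets marked by KDR, DCN, SLC6A4 and THRA at 1/4 of the highest CPM among clusters of at least 50 nuclei. Fractions of 1/2 and 1/4 and any 3 markers of the binucleate list were run as alternatives, likewise chosen after seeing the data. A cluster led by genes of another class among its top 10 stayed unnamed; this rule, and the match of CYP19A1 to CYP19, were applied after a first naming had been seen.

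Levels are sums of raw counts over nuclei, scaled to the library total of those nuclei (CPM), with exact Poisson intervals, and shares have Clopper-Pearson intervals. No p-value was computed, since each stage is 1 library. Named genes are the 10 highest and 10 lowest by log2 CPM ratio between D120 and D50 with a ratio of at least 2, at least 50 UMIs in the higher library and a symbol. Within a class the CPM also had to reach that over all nuclei of the library. Mitochondrial, ribosomal protein and haemoglobin genes were left out of the ranking, members of fixed lists with at least 20 UMIs could be named as examples, and a library at 0 was set to 3 UMIs. A list with at least 5 measured members was placed among 10000 random lists matched on mean expression, as a description of these libraries. Lists with fewer measured members received values only, and none of the 21 amino acid transport genes had a symbol.

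The ratio and list steps were tested on simulated data with 200 changed genes. For D120 against D50, over 13058 genes, true log2 ratios of 1 and 2 came back with medians of 1.00 and 1.97. Intervals covered the true value for 91.6% of unchanged genes, below the nominal 95%, since changed genes shift the totals. For genes with true log2 ratios of 1 and 2 it was 94% and 82%. Of 200 unchanged lists, 4.50% fell outside the central 95%. Simulated genes varied independently, so this does not cover lists whose genes move together. Alternatives covered filters, doublets, clustering resolution, per-library clustering, naming of single nuclei, scaling, UMI minimums and subtraction of 10% free RNA.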

Results

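Single-nucleus RNA sequencing had been carried out on placenta of Hu sheep, a breed kept for its large litters, at gestation days 50, 80 and 120 (D50, D80 and D120). Each stage was 1 library, so stage and library cannot be separated and no difference between stages was tested. Intervals in parentheses are 95% intervals and cover counting error only. They are exact, except those of the list median gap and of the matrix gene ratio near the end, which come from Poisson redraws. The libraries held 42716937, 31020473 and 23941649 UMIs over 8475, 10751 and 7887 barcodes. After filtering, 7760, 9781 and 7370 nuclei remained, with medians of 3802.5, 2338 and 2585 UMIs. The files pair few gene identifiers with a symbol, and 782 symbols could be used. Every gene named here comes from that part.

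Trophoblast, the epithelial lineage of the placenta that meets the maternal tissue, made up most nuclei that could be named. Besides trophoblast, only macrophages, T or NK cells and maternal uterine epithelium had the 3 detected markers that naming needs. Fibroblast and endothelium had 1 each, so they could not be named, and the named shares do not give the make-up of the tissue. Clusters carrying at least 3 of the markers EPCAM, TFAP2A, HAND1, PEG10 and PPARG, without high PAG genes, were called other trophoblast-like. They held 44.1% (43 to 45.2) of nuclei at D50, 72.7% (71.8 to 73.6) at D80 and 68.8% (67.8 to 69.9) at D120. Clusters high in PAG4, PAG6 and PAG9, pregnancy-associated glycoproteins made by binucleate trophoblast cells, were called PAG-high. They held 16.5% (15.7 to 17.4), 14.6% (13.9 to 15.3) and 11.8% (11.1 to 12.5). Macrophage-like nuclei, with C1QA, MRC1, CD14 and CD86, formed cluster 17 and were 6.24% (5.71 to 6.80) of D50 nuclei. No nucleus of the D80 or D120 library fell in that cluster, which does not bound their macrophage shares. Naming single nuclei by marker score gave 0.286% and 1.26% there. The complement gene C1QA itself stood at 45.9, 1.37 and 6.62 CPM over all nuclei at D50, D80 and D120. In the later libraries MRC1 and C1QA were among the leading genes of cluster 14, with GNLY and LGALS15. It carried 4 trophoblast markers as well and stayed unnamed, holding 0.0773%, 3.87% and 3.50% of nuclei.

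The PAG-high share depended on the clustering, with values given further below, and on a naming rule set after the cluster values were seen. CYP11A1, HSD3B1, STAR and CYP19 had been fixed as binucleate markers together with the PAG genes, but they were highest in clusters with low PAG levels. Requiring all 3 PAG genes gave the shares above. Taking any 3 markers of the fixed list gave 16.6%, 62.1% and 69.6%, the opposite order. The difference is clusters 0 and 15, with 42% and 5.06% of D80 nuclei, and clusters 1, 5 and 23, with 37.7%, 17.3% and 2.35% of D120 nuclei, which carry the steroid genes. MET was the single uninucleate marker with a symbol, so uninucleate nuclei could not be named and no binucleate share of trophoblast was computed. The support fraction, also set after values were seen, kept cluster 16 out of the trophoblast classes. It held 6.33% of D50 nuclei, no D80 or D120 nucleus, and was led by CDK1 and AURKA. The same genes led cluster 15, at 5.06% of D80 nuclei, and cluster 23, at 2.35% of D120 nuclei, both counted as other trophoblast-like.

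**Figure D1:**
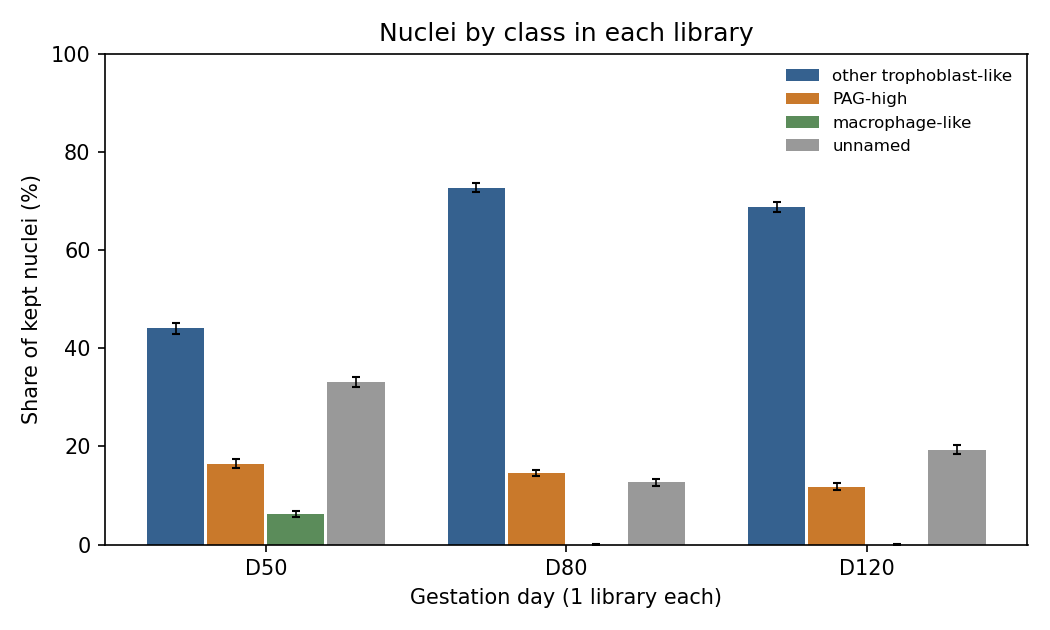
Bars give the share of kept nuclei (percent, vertical axis) in each class for the D50, D80 and D120 libraries, and error bars give exact binomial 95% intervals covering counting error only. Other trophoblast-like nuclei range from 44.1% at D50 to 72.7% at D80.

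D50 nuclei shared few clusters with the later libraries, while clusters 4, 8, 10, 14, 18, 19 and 22 held D80 and D120 nuclei together. Clusters 0, 1 and 2, the largest, drew 99.3%, 99% and 99.9% of their nuclei from D80, D120 and D50 respectively. The other trophoblast-like class consisted mainly of clusters 2, 9 and 20 at D50, 0, 3 and 7 at D80, and 1, 5 and 12 at D120. The PAG-high class consisted of cluster 6 at D50 and of clusters 4 and 10 at D80 and D120. Values compared within a class therefore come from different clusters. Clusters with fewer than 3 markers of any 1 class stayed unnamed, and some were grouped by a single gene. KDR, the main VEGF receptor of endothelium, marked clusters 8 and 21. DCN, a matrix proteoglycan of fibroblasts, marked clusters 13 and 25. Cluster 22 was joined to these as the DCN-high set with a lower DCN level of 396 CPM, against 1426 in cluster 13 and 2813 in cluster 25, and FGF10, EDNRA and AGTR1 led it. SLC6A4, the serotonin transporter and not a fixed marker, was highest in clusters 11 and 18, which also carried HAND1 and MET, as most clusters did. SERPINA14, a fixed marker of maternal uterine epithelium, led cluster 18 at 246 CPM, its highest level, against 2.40 in cluster 11.

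Over all nuclei, most measured steroid synthesis genes were higher at D120 than at D50. STAR, which moves cholesterol into mitochondria, stood at 12.9, 39.1 and 255 CPM at D50, D80 and D120. CYP11A1, the side-chain cleavage enzyme, stood at 94.2, 305 and 569.8 CPM. CYP19, aromatase, stood at 66.1, 201 and 516 CPM, and HSD3B1 at 78.8, 171 and 239 CPM. Of the 20 genes of the steroid list 8 were measured. Of these, 5 were at least 2-fold higher and 2 at least 2-fold lower, the latter being HSD11B1 and NR5A2. For this list the median log2 ratio of its 8 measured members was 1.44, at percentile 99.99 of the 10000 random lists. PTGS2, a prostaglandin synthase, was 33.3-fold higher at D120, with a log2 ratio of 5.06 (4.73 to 5.40). GHR, the growth hormone receptor, was 5.19-fold higher. AQP1, a water channel, was 27.6-fold higher. VEGFA, the main angiogenic growth factor, stood at 86.2, 193 and 378 CPM, and the glucose transporter gene SLC2A3 at 199, 299.6 and 507 CPM.

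Over all nuclei, 8 of the 32 listed extracellular matrix genes were measured. Of these, 6 were at least 2-fold lower at D120 and 1 at least 2-fold higher. For the extracellular matrix list the median log2 ratio of its 8 measured members was -3.17, at percentile 0 of the 10000 random lists. TIMP1, a metalloproteinase inhibitor, stood at 864, 18 and 14 CPM, TIMP3 at 3993, 335 and 351 CPM and DCN at 189.7, 2.67 and 7.98 CPM. TIMP2 was near level, at 290.1, 161 and 315 CPM, and MMP2 was the member at least 2-fold higher at D120, at 0.596, 2.59 and 5.30 CPM. For growth factors and receptors the median log2 ratio of its 7 measured members was -2.14, at percentile 0.01 of the 10000 random lists, with 4 members at least 2-fold lower and 2, IGFBP4 and GHR, at least 2-fold higher. IGFBP3 stood at 76.7, 4.08 and 0.516 CPM. MMP7 had no UMI at D120 and was 446-fold lower with that library set to 3 UMIs, which is not a lower bound. NPPB was 144-fold lower. At D80 the matrix list lay lower still: its median against D50 was -4.18. The DCN-high set held 729, 30 and 181 nuclei at D50, D80 and D120, and in other trophoblast-like nuclei the matrix list median was -1.90, which turned to 0.47 with 10% free RNA subtracted. SPARC turned then, while DCN, TIMP1 and TIMP3 stayed lower, at -3.23, -4.65 and -1.89.

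The other lists with enough members lay nearer the centre over all nuclei. For interferon response and immune tolerance the median log2 ratio of its 8 measured members was -0.48, at percentile 5.08 of the 10000 random lists, and B2M stood at 1259, 480.1 and 295 CPM. For placental hormones and binucleate products the median log2 ratio of its 6 measured members was -0.73, at percentile 4.18 of the 10000 random lists. For lipid uptake and metabolism the median log2 ratio of its 10 measured members was 0.15, at percentile 70.8 of the 10000 random lists. For TGF-beta and BMP signalling the median log2 ratio of its 9 measured members was 0.39, at percentile 92.2 of the 10000 random lists, with ACVR2A at 163, 245 and 334 CPM. Mitochondrial genes summed to 11637, 8181 and 2592 CPM. Ribosomal protein genes with a symbol summed to 2828, 2547 and 1188 CPM.

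Within other trophoblast-like nuclei 5 of 7 measured steroid genes were at least 2-fold higher at D120 and 1, HSD11B1, at least 2-fold lower. STAR had 20.1 CPM (17.8 to 22.5) at D50 and 307 CPM (298 to 315) at D120, a log2 ratio of 3.93 (3.76 to 4.11). CYP11A1 stood at 156, 375 and 709.5 CPM over the stages, CYP19 at 104, 254 and 652 CPM and HSD3B1 at 121, 208 and 294 CPM. For the list the median log2 ratio of its 7 measured members was 1.28, at percentile 99.98 of the 10000 random lists, and with a 50 UMI minimum it was 2.18 over 5 members. The steroid-carrying clusters 1, 5 and 23 belong to this class at D120 only under the PAG rule set after cluster values were seen. The list was not recomputed under the any-3-markers rule. In cluster 12, the main D120 cluster left under that rule, STAR stood at 183 CPM, CYP11A1 at 132, CYP19 at 85.2 and HSD3B1 at 73.0. Of these only STAR exceeded the D50 value of the class. STAR and CYP11A1 were also detected in KDR-high nuclei, a set marked by an endothelial gene. STAR stood there at 6.29, 24.4 and 123 CPM and CYP11A1 at 32.1, 179 and 243 CPM. PTGS2 was 95.5-fold higher at D120, GHR 13.6-fold, and SLCO2A1, a prostaglandin transporter, 5.69-fold. Of placental hormones and binucleate products, 5 of 5 measured members were at least 2-fold lower at D120, with a median log2 ratio of -1.87 at percentile 0.08. They are INHBA, at 14.7, 1.68 and 2.30 CPM, GH, and PAG4, PAG6 and PAG9, by whose low levels this class was set apart. PAG4 stood at 584, 1117 and 268 CPM here and at 400.4, 1423 and 339 CPM in KDR-high nuclei, and PAG6 was similar in both. The PAG genes here may thus be background, which was not tested further. INHBA and GH were not compared in this way, and the list is not read as a difference in expression. Of growth factors and receptors, 3 of 6 were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.20. SLC15A1, CYP1A1, BCO2 and GMPR were also among the highest ratios, each under 20 CPM in every library. Lower at D120 were NPPB (227-fold), MT3, a metallothionein, ANKRD1 (26.5-fold) and PTGS1. NPPB, ANKRD1 and PTGS1 were among the leading genes of cluster 20, which held 305 D50, 4 D80 and 2 D120 nuclei. ANKRD1 and PTGS1 may thus mark that cluster more than the class. NPPB was also among the leading genes of cluster 2, which held 2157 D50 nuclei. CFTR, a chloride channel, stood at 185, 198 and 63.3 CPM. FOS, an early stress-response gene, stood at 38.8, 22.2 and 12.6 CPM.

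**Figure D2:**
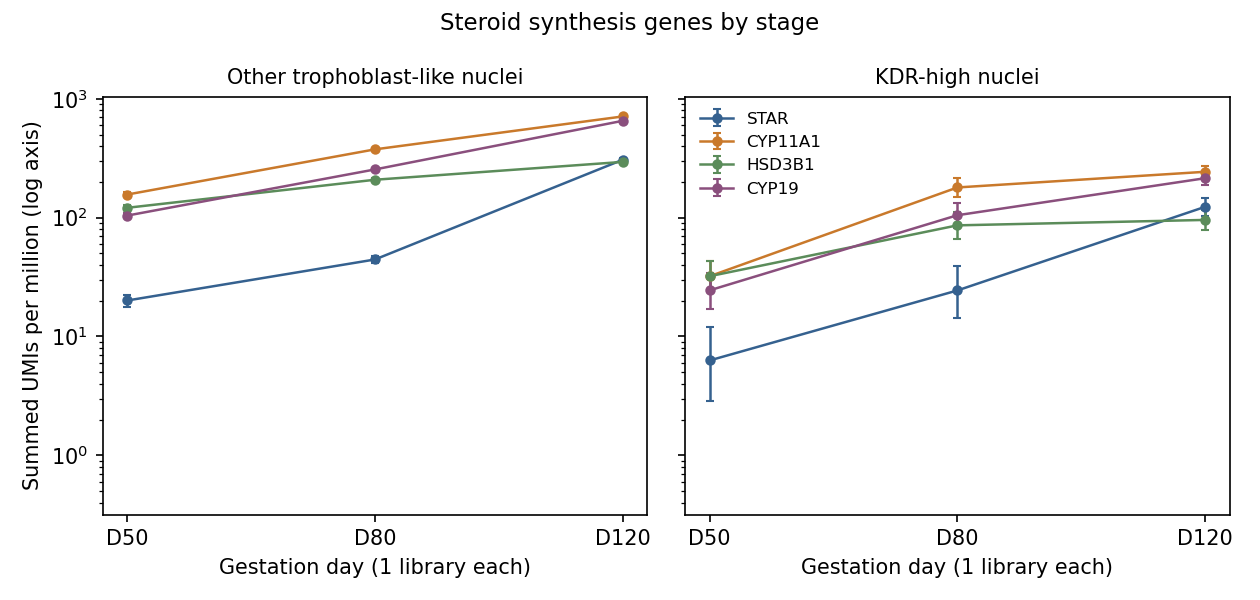
Points give CPM (log axis) of STAR, CYP11A1, HSD3B1 and CYP19 at D50, D80 and D120 in other trophoblast-like nuclei (left) and KDR-high nuclei (right), with exact Poisson 95% intervals covering counting error only. STAR reaches 307 CPM at D120 on the left and 123 CPM on the right.

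Within PAG-high nuclei the PAG genes, which define the class, are not reported as a result. Read sharing between these close paralogs was not examined. PPARG, a lipid-sensing nuclear receptor that is also a naming marker, stood at 4006, 5155 and 7260.0 CPM. ADIPOQ, which encodes adiponectin, was 12.5-fold higher at D120, RAB4A 5.97-fold and the sialyltransferase ST6GAL1 4.17-fold. SLC7A11, the cystine transporter, stood at 49.9, 30.1 and 5.71 CPM, CRYAB at 582, 446 and 157 CPM and B2M at 1290.4, 657 and 408 CPM. RTP4 was 19.6-fold lower at D120. Of interferon response and immune tolerance genes, 5 of 8 were at least 2-fold lower, with a median of -1.26 at percentile 0.87. With a 50 UMI minimum it was -0.72 over 6 members, at percentile 9.18, within the random lists. Of extracellular matrix genes, 5 of 6 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -1.29 at percentile 0.2. Free RNA as a source was not tested for this list in PAG-high nuclei. DCN stood at 22.4 CPM in cluster 6, which supplied the D50 nuclei, near the 29.7 of cluster 9 and 37.8 of cluster 2. In the DCN-marked cluster 13 it stood at 1426 CPM. The list is therefore not read as a difference in expression in PAG-high nuclei. The growth factor and receptor list had a median of -1.02 at percentile 1.11. The steroid list, taken up further below, had a median of 1.68 at percentile 100. Membership of this class moved with the clustering. ATP1A1, at a log2 ratio of 1.04, had -1.0 when each library was clustered alone and 3.79 with nuclei of at least 500 genes.

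In the unnamed sets, KDR-high nuclei numbered 344, 376 and 618. AQP1 stood there at 24.5, 379 and 569 CPM and IGFBP4 at 72.7, 251 and 327 CPM. IGFBP3 stood at 1295, 21.5 and 0.861 CPM, TIMP3 at 5681, 367 and 347 CPM and SELE, an endothelial adhesion gene, at 160.0, 0 and 0 CPM. Cluster 21, led by IGFBP3 and SELE, supplied most D50 nuclei of this set, and cluster 8, led by AQP1, the later ones. In DCN-high nuclei, compared between D50 and D120 as D80 had 30, MEF2C stood at 11.5 and 307 CPM and the glucocorticoid receptor gene NR3C1 at 64.1 and 520.1 CPM. TIMP3 stood at 23590.3 and 449 CPM and SPP1 at 1197 and 11.2 CPM. The D50 nuclei came almost all from clusters 13 and 25 and the D120 nuclei from cluster 22, which MEF2C helps lead. Differences in both sets are therefore between clusters of different libraries.

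Of the cell cycle list only CDK1 had a symbol, so the list could be read from 1 gene. CDK1 stood at 23.5 CPM (22 to 25.2) at D50, 23.7 (21.9 to 25.7) at D80 and 17.2 (15.5 to 19.1) at D120. After thinning to 1000 UMIs, 4 of 7675, 5 of 9343 and 4 of 6724 nuclei had at least 2 CDK1 UMIs, too few to compare, and 85, 438 and 646 shallower nuclei were left out. AURKA, a mitotic kinase outside the list and named after its values were seen, stood at 28.7, 24.6 and 11.6 CPM over all nuclei. It was highest in clusters 15, 16 and 23, at 81.9, 90.2 and 84.9 CPM. Unthinned shares with at least 2 CDK1 UMIs were 1.65%, 0.521% and 0.773%, a measure that favours the deeper D50 library. With at least 1 CDK1 UMI after thinning, a count chosen after seeing the data, shares were 2.02%, 2.25% and 1.35%, another order, so no order is read from the unthinned shares.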

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

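The marker fractions 1/2 and 1/4, the any-3-markers rule and the 1-UMI cycling count were chosen after seeing the data, and the other alternatives before. Class shares were the least stable results. Values follow for D50, D80 and D120, against 60.6%, 87.3% and 80.6% trophoblast-like and 16.5%, 14.6% and 11.8% PAG-high nuclei as reported. With Leiden resolution 0.5, trophoblast-like nuclei were 67.7%, 87.5% and 81% and PAG-high nuclei 16.5%, 14.5% and 11.8%. With Leiden resolution 2, trophoblast-like nuclei were 54.9%, 84.5% and 60.1% and PAG-high nuclei 11.1%, 14.4% and 1.80%. With no filter, trophoblast-like nuclei were 55.3%, 86.8% and 80.2% and PAG-high nuclei 11%, 12.4% and 11.4%. With at least 500 genes per nucleus, trophoblast-like nuclei were 56.5%, 91.2% and 83.7% and PAG-high nuclei 12.1%, 12.8% and 6.68%. With doublets kept, trophoblast-like nuclei were 68.2%, 91% and 82.7% and PAG-high nuclei 17.2%, 13.4% and 12.2%. With each library clustered alone, trophoblast-like nuclei were 66.9%, 90.9% and 80.2% and PAG-high nuclei 10.2%, 13.7% and 6.13%. With single nuclei named by score, trophoblast-like nuclei were 81%, 95.2% and 96% and PAG-high nuclei 23.7%, 37.3% and 45.2%. With the 1/2 marker fraction, trophoblast-like nuclei were 20.5%, 13.9% and 10.7% and PAG-high nuclei 16.5%, 0.0204% and 0.0136%. With the 1/4 marker fraction, trophoblast-like nuclei were 70.1%, 94% and 89.9% and PAG-high nuclei 16.5%, 14.6% and 11.8%. With any 3 binucleate-list markers, trophoblast-like nuclei were 60.6%, 87.3% and 80.6% and PAG-high nuclei 16.6%, 62.1% and 69.6%. The trophoblast-like share was lowest at D50 in all of these except the 1/2 fraction. The order of the PAG-high shares was not stable, and its cause was not tested beyond the naming rules.

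The steroid list median in other trophoblast-like nuclei, 1.28 as reported, was 1.18 as a mean over nuclei, 1.16 with at least 500 genes and 2.18 with a 50 UMI minimum. It was not recomputed under the other naming rules. The tissue extracellular matrix median was -2.64 as a mean over nuclei. Its median in other trophoblast-like nuclei, -1.90 as reported, turned to 0.474 after subtracting 10% free RNA, because SPARC (-1.90 to 0.51) and MMP14 (-0.40 to 2.46) turned while DCN stayed at -3.23, TIMP1 at -4.65 and TIMP3 at -1.89. ATP1A1 in PAG-high nuclei turned to -1.0 with per-library clustering; the cause was not tested. That class was also where a setting moved the median of all genes most, by -0.26 with at least 500 genes. For list medians, 338 alternatives stayed within the counting interval, 78 left it and 1 was labelled reversed, a label that misses some sign changes. For named genes the numbers were 290, 61 and 1, and for cycling shares 23 stayed and 25 left it. Macrophage-like shares at D80 and D120 were 0.286% and 1.26% with single nuclei named by score. Other settings were not run for the binucleate share, which could not be computed. With a 200 UMI minimum, 8 of the 10 higher and 7 of the 10 lower named genes of other trophoblast-like nuclei stayed named, and with no minimum 9 and 4. Of the 10 higher ones, 3 and 1 stayed in KDR-high and 2 and 1 in DCN-high nuclei, and of the 9 in SLC6A4-high nuclei 4 and 3. Of the 10 lower ones in THRA-high nuclei 0 and 4 stayed. Of the 10 lower ones, 10 and 10 stayed in DCN-high, 6 and 8 in KDR-high and 5 and 7 in SLC6A4-high nuclei. Dependence on the minimum was thus greatest for the higher genes of these sets and the lower genes of THRA-high nuclei. Depth limits genes under about 50 UMIs and small sets. No paired analysis was possible because each stage has 1 library.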

Other observations

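All 5 tests of explanations reported here were chosen after the patterns were seen. The sets marked by SLC6A4 and THRA were not described above. SLC6A4-high nuclei numbered 841, 173 and 304, from cluster 11 at D50 and cluster 18 later. TIMP2, a metalloproteinase inhibitor, stood there at 1320.1, 2437 and 5018 CPM, SHROOM4 at 14.1, 248 and 367 CPM and SLC14A1, a urea transporter, at 12.5, 23.5 and 104 CPM. SFRP2, a secreted Wnt regulator, stood at 626, 23.5 and 26 CPM and PRNP, the prion protein gene, at 191, 67 and 45.4 CPM. SFRP2 and PRNP lead cluster 11 and the former genes cluster 18, so these are differences between clusters. THRA-high nuclei numbered 163, 282 and 67, and FTH1, a ferritin subunit, stood at 285, 156 and 55.4 CPM.

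Most measured steroid genes were higher at D120 in other trophoblast-like nuclei, as named under the PAG rule. A scaling factor common to all genes would not part the list from the rest. The list median exceeded the median of all measured genes by 1.31 (1.24 to 2.00, log2). Both medians were known when this test was set, so it restates the list median and is no independent evidence. STAR, CYP11A1, CYP19 and HSD3B1 had a median CPM 3.69 times that of the remaining D120 nuclei. That goes against free RNA from other nuclei as the whole source, but only for the class as named. The steroid-carrying clusters 1, 5 and 23 are in it under the PAG rule, set after their values were seen. The ratio was thus no independent evidence, and it was not computed under the any-3-markers rule, which moves these clusters out. The list median was also 2.92 in KDR-high and 2.83 in DCN-high nuclei, from different clusters at D50 and D120. Steroid gene expression in these nuclei may differ by gestation stage, a hypothesis that 1 library per stage cannot separate from the library. It also rests on a naming rule set after cluster values were seen. In PAG-high nuclei, where the list median was 1.68, the same genes had a median of 0.546 times their level in KDR-high nuclei at D120. That lay outside the range set for free RNA and under the bound against it. The range took no account of depth, and equal free RNA per nucleus gives a lower CPM in deeper nuclei. Median UMIs, over all libraries, were 3289 and 2668 in PAG-high clusters 4 and 10, against 1581 in KDR-marked cluster 8. A ratio under 1 is thus no evidence against free RNA, and free RNA and expression cannot be told apart there.

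Of 7 measured extracellular matrix genes, 4 were at least 2-fold lower at D120 within other trophoblast-like nuclei, namely DCN, SPARC, TIMP1 and TIMP3, and MMP2 was higher. Free RNA from DCN-high nuclei could be the source at D50. The ratio of CPM between these sets differed 15.4-fold over all 5 measured members, but TIMP2 set that value and was not lower at D120, and the test was narrowed after that was seen. Over the 4 members that were lower, it differed 3.18-fold (2.67 to 3.88), an interval spanning the 3-fold bound. The interval does not cover the choice of the highest and lowest members. With an assumed 10% of free RNA subtracted, SPARC turned to 0.51, while DCN, TIMP1 and TIMP3 stayed lower at -3.23, -4.65 and -1.89. Free RNA and expression in trophoblast cannot be told apart for these genes, because the interval spans the bound and the free RNA share was assumed, not measured.

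The median log2 ratios of mitochondrial and of ribosomal protein genes were below 0 at D120 in every one of the 7 sets examined, counting all nuclei as a set. The highest of the 14 medians was -0.63. In other trophoblast-like nuclei the medians were -2.07 and -1.35, and in PAG-high nuclei -2.31 and -1.44. This is consistent with less cytoplasmic RNA kept with the nuclei of the D120 library. Lower levels of abundant cytoplasmic transcripts such as FTH1, at 262, 191 and 99.3 CPM over the stages, may then partly reflect preparation, which 1 library per stage leaves open.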
